A study of Mus musculus with 8 samples.

How the data were processed

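Gene expression was measured by bulk RNA sequencing in 8 pieces of mouse liver, 4 labelled tumour and 4 labelled non-tumour. Per the labels' protocols, tissue was snap-frozen, lysed in Trizol, purified on a Qiagen column and made into libraries with an Illumina mRNA kit. The deposited files hold raw read counts per gene, 1 file per sample with 54838 genes. Per the file headers, the authors counted reads with featureCounts 1.6.2 over exons of the Ensembl release 95 annotation of GRCm38 with strand setting 2 and without counting multi-mapping reads. The submitters' processing notes also name STAR 2.5.0, Subread 1.6.2 and GRCm38. Reads shared by near-identical paralogs (the Gstp, H2-Q, Mup and Cyp2 families) are left out by such counting, so their levels are uncertain. Trimming and read length are not given in the sources used here.

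Gene symbols came from a reference table for the same build, which matched 54723 of the 54838 gene IDs; 203 IDs shared a symbol with another. Totals per library ran from 15446690 to 21977052 counts. Groups were taken from the labels. Similarity between libraries was measured for each pair by the chi-square of gene counts, over genes with 20 or more reads in the pair, and pairs under 10 per degree of freedom were called near-identical, a limit set after seeing the data. Counts of such libraries were summed into 1 profile where the text says that they were counted once.

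The tests, gene lists, cell type markers, rule for named genes and alternatives were fixed before the data were examined. Differences between tumour and non-tumour were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation and glmQLFTest) after TMM scaling and filterByExpr (minimum count 10, minimum total 15), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM values use TMM-scaled library sizes. Standard errors are the log2 fold change divided by the root of the F statistic. Lists with at least 3 tested members were compared with other genes by camera of limma 3.58.1, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. List scores are means over members of log2 CPM (prior count 2) minus the mean of the non-tumour profiles. Spread used the distance of each library to its group centroid over the 500 genes with the largest variance within groups.

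Genes were named by this rule: a fixed panel (Afp, Gpc3, Igf2, H19, Glul, Mki67, Alb, Cps1, Cyp7a1 and Col1a1); the 6 largest differences in each direction among genes past the threshold with a mean of at least 1 CPM, groups that do not overlap and a symbol that is not a predicted-gene name; the 3 most abundant genes past the threshold in each direction; and for a list up to 2 of its members with the lowest p-values, or 3 where camera called it. Spp1, Tspan8, Vsig4 and the other list examples in the text come from that last part, chosen among its examples after the values were seen. Its remaining examples are not reported here. Clock genes, immunoglobulin V genes and imprinted genes named in the closing section were chosen after their values were seen.

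Alternatives were DESeq2 size factors, library size and upper-quartile scaling, other expression filters, DESeq2 1.42.0, limma voom with sample quality weights, a replicate block, leaving out the 10 most abundant genes, a test against a 1.5-fold change, camera with an estimated correlation, fry, other gene numbers and prior counts for the spread, and leaving out each library. Counting near-identical libraries once, with and without tumour 3, was added after seeing the data, as were DESeq2 and voom on those profiles. The scripts were tested on simulated data. With 4 against 4 separate libraries and 12728 to 12748 genes, 61.2% of genes changed by 1 log2 unit and 99.2% of those changed by 2 were recovered, and 5.87% of the calls were false. With 3 against 2 and 12867 to 12871 genes the shares were 26% and 97.4%, and 4.19% were false. With no true change and libraries repeated as in the data, the 8-library fit made a median of 331 calls per run, and the fit with them counted once made 0 to 1. All simulations gave every gene the same dispersion (0.0611) and drew genes independently, and repeated libraries differed by counting noise alone. These shares and counts need thus not hold for the real data.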

Results

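RNA from 8 liver pieces of male C57BL/6J mice was measured by bulk RNA sequencing. The mice had received the liver carcinogen diethylnitrosamine (DEN) by intraperitoneal injection on day 15 of life and were fed a high-fat diet with SW, an abbreviation the labels do not expand, up to a 30-week time point. The labels give 30 weeks both as the length of the diet and as the time after the injection, so the age at sampling is uncertain. The labels divided the pieces into 4 tumours and 4 non-tumour pieces, numbered 1 to 4 in each group, and do not say whether they came from separate mice, so p-values measure the spread between these samples only. The reads assigned to genes numbered 15446690 in non-tumour 3, the shallowest library, and 21977052 in tumour 1, the deepest. Albumin (Alb) was the most abundant gene in every library, with 7.57% of the counts in non-tumour 1 and 13.9% in tumour 1 at the extremes. Mitochondrially encoded genes took 5.01% to 6.66% of the counts. A count of 0 (up to 3 counts) allows a level of up to 0.137 CPM (read counts scaled to a common library size) in the deepest library and 0.205 CPM in the shallowest, for counting error only.

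The 8 libraries held 5 distinct expression profiles. Tumour 2 and tumour 4 were nearly the same, and so were non-tumour 2, 3 and 4. In these 4 pairs the chi-square per degree of freedom of the gene counts, which is 1 for counting noise alone, lay between 1.58 and 3.28, and in the other 24 pairs between 71.7 and 165. Among genes with 1000 or more reads the log2 ratio had an SD of 0.057 to 0.083 in the near-identical pairs and of 0.32 to 0.53 in the others. The near-identical libraries thus differed by slightly more than counting noise, but far less than any other pair of the same group. They were counted as 1 sample in every mean ± SD of a gene's level below, so that n = 3 tumour profiles (1, 2/4 and 3) and n = 2 non-tumour profiles (1 and 2/3/4). The tests were fitted over the 8 libraries as planned, and each main count is given again with near-identical libraries counted once, a setting chosen after seeing the data.

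**Figure D1:**
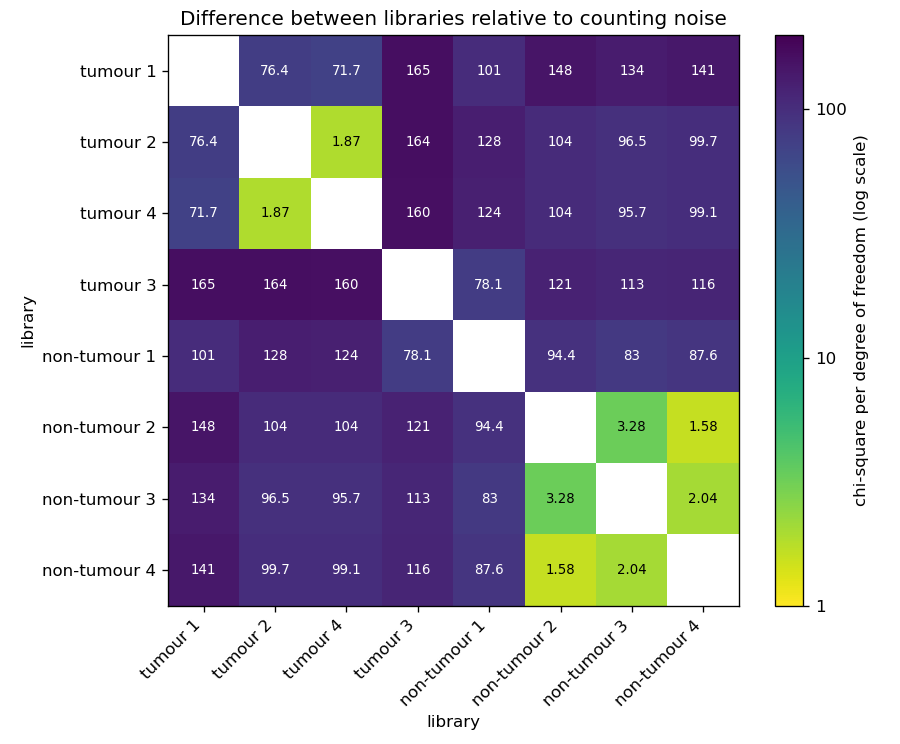
Chi-square per degree of freedom of the gene counts for each pair of libraries, with both axes listing the 8 libraries and the colour on a log scale. The 4 near-identical pairs lie between 1.58 and 3.28, and the other 24 pairs between 71.7 and 165.

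The comparison of tumour with non-tumour tissue asks which genes distinguish the tumours from non-tumour liver. The fetal and liver tumour marker genes Afp, Gpc3 and H19 were far more abundant in tumours 1, 2 and 4 than in any non-tumour library. Afp, the fetal serum protein alpha-fetoprotein (chromosome 5, 90490737 to 90508907, GRCm38), stood at 842, 425 and 427 CPM in them, against 1.46 CPM in tumour 3, 19.4 CPM in non-tumour 1 and 4.71 to 5.06 CPM in the other non-tumour libraries. Gpc3, a cell-surface proteoglycan (chromosome X, 52272426 to 52613950), stood at 192, 166 and 163 CPM in tumours 1, 2 and 4, at 1.20 CPM in tumour 3 and at 4.37 to 7.72 CPM in non-tumour tissue. H19, an imprinted long noncoding RNA (chromosome 7, 142575529 to 142578143), stood at 407, 337 and 352 CPM in the same 3 tumours, at 0.127 CPM in tumour 3 and at 63.2 CPM in non-tumour 1. None of the 3 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (Afp log2 fold change 5.62, SE 1.35, adjusted p = 0.0999; Gpc3 4.58, SE 1.05, adjusted p = 0.0941; H19 3.56, SE 1.34, adjusted p = 0.213). Without tumour 3 all 3 passed over the other 7 libraries (Afp adjusted p = 0.00136, Gpc3 1.03e-05, H19 0.0125), but with near-identical libraries also counted once only Gpc3 did (0.0290; Afp 0.136, H19 0.311). Igf2, the neighbour of H19 and also imprinted, had at most 1 read in a library and was not tested.

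In that test over the 8 libraries, 56 of 12880 genes had an adjusted p under 0.05, 24 of them higher and 32 lower in tumours, and 27 of the 56 differed by 2-fold or more. These calls do not stand as evidence of a difference between the groups. With near-identical libraries counted once, edgeR called 0 of 13650 genes, 451 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.995; on these profiles limma voom called 0 genes (1086 with an unadjusted p under 0.05) and DESeq2 called 2 (577), Ankrd33b and Dock8, named after their values were seen. In simulated libraries with no true change, repeated as in these data, the 8-library fit called 181 to 447 of 12711 to 12764 genes in each of 20 runs. The simulations gave every gene the same dispersion and drew genes independently. Their repeats differed by counting noise alone, whereas the real near-identical pairs had a chi-square per degree of freedom of 1.58 to 3.28. These counts need thus not hold for the real data. Without tumour 3 the count over 7 libraries was 1798, and it was 5 with near-identical libraries also counted once (Gpc3, Cpe, 5330417C22Rik, Tcf24 and Ocstamp, all higher, the last 4 named after their values were seen). It was 766 without non-tumour 1 and 0 without tumour 2, tumour 4 or non-tumour 2, 3 or 4, with 1570 to 1796 genes at an unadjusted p under 0.05. The genes below are therefore described by their levels in the tumour and non-tumour profiles or by log2 fold changes. Unless another setting is named, fold changes and SEs are those of the 8-library fit, which takes near-identical libraries as separate replicates.

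Of the genes with the largest differences among the 56, Hao2, a peroxisomal hydroxyacid oxidase, averaged 4.00 ± 1.52 CPM in tumours (SD, n = 3). In non-tumour tissue it averaged 0.713 ± 0.490 CPM (SD, n = 2). Its log2 fold change in edgeR was 2.97 over the 8 libraries (SE 0.45, adjusted p = 0.0384) and 2.56 counted once (SE 0.59, adjusted p = 0.995). H2-Q1 averaged 19.9 ± 7.51 against 4.52 ± 3.24 CPM and H2-Q2 1.94 ± 0.878 against 0.458 ± 0.00631 CPM. Both are class Ib genes of the MHC with close paralogs, and reads that mapped to more than 1 place were not counted, so their levels are uncertain. Slc22a29, of the organic anion transporter family, Sccpdh and the imprinted zinc finger gene Peg3 were the other 3 of the 6 largest on the higher side. Their 8-library log2 fold changes were 2.08 (SE 0.27), 1.84 (SE 0.31) and 1.55 (SE 0.22). Counted once they were, in order, 1.84 (SE 0.41), 1.79 (SE 0.47) and 1.62 (SE 0.34). On the lower side were Cyp26b1, which degrades retinoic acid, Cspg5, Obp2a and the glutathione transferase Gstp2 (a near copy of Gstp1). The fatty acid elongase Elovl3 and the complement gene C8b followed. Their 8-library log2 fold changes were -2.85 (SE 0.41), -2.31 (SE 0.38), -2.23 (SE 0.36), -2.15 (SE 0.34), -1.82 (SE 0.27) and -1.50 (SE 0.24). Counted once they were, in order, -2.45 (SE 0.55), -2.01 (SE 0.52), -2.12 (SE 0.49), -1.77 (SE 0.47), -1.61 (SE 0.37) and -1.23 (SE 0.33).

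The most abundant of the 56 genes on the higher side were Fabp2, a fatty acid binding protein, at 199 ± 66.3 against 82.6 ± 17.6 CPM, Vnn3 at 102 ± 24.7 against 54.0 ± 0.338 CPM and Angptl8, a regulator of lipoprotein lipase, at 70.1 ± 18.5 against 36.0 ± 2.73 CPM (SD, n = 3 and n = 2). On the lower side they were Gnmt, glycine N-methyltransferase, at 564 ± 30.7 against 1179 ± 380 CPM, Ass1, a urea cycle enzyme, at 556 ± 28.6 against 1039 ± 359 CPM and the complement gene C9 at 292 ± 50.5 against 579 ± 226 CPM. Of the fixed panel, Cps1, the first urea cycle enzyme, stood at 1225 ± 269 CPM in tumours and 1958 ± 634 CPM in non-tumour tissue (adjusted p = 0.115). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 29.6 ± 12.2 and 64.5 ± 15.3 CPM (adjusted p = 0.0910), and Alb at 111070 ± 26698 and 76755 ± 4888 CPM (adjusted p = 0.264). Glul, glutamine synthetase, had a log2 fold change of 0.06 (SE 0.22, adjusted p = 0.922), Mki67, a proliferation marker, of 0.65 (SE 0.46, adjusted p = 0.501) and Col1a1, a fibrillar collagen, of 0.43 (SE 0.33, adjusted p = 0.534). The direction of Glul turned with near-identical libraries counted once, to -0.08.

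**Figure D2:**
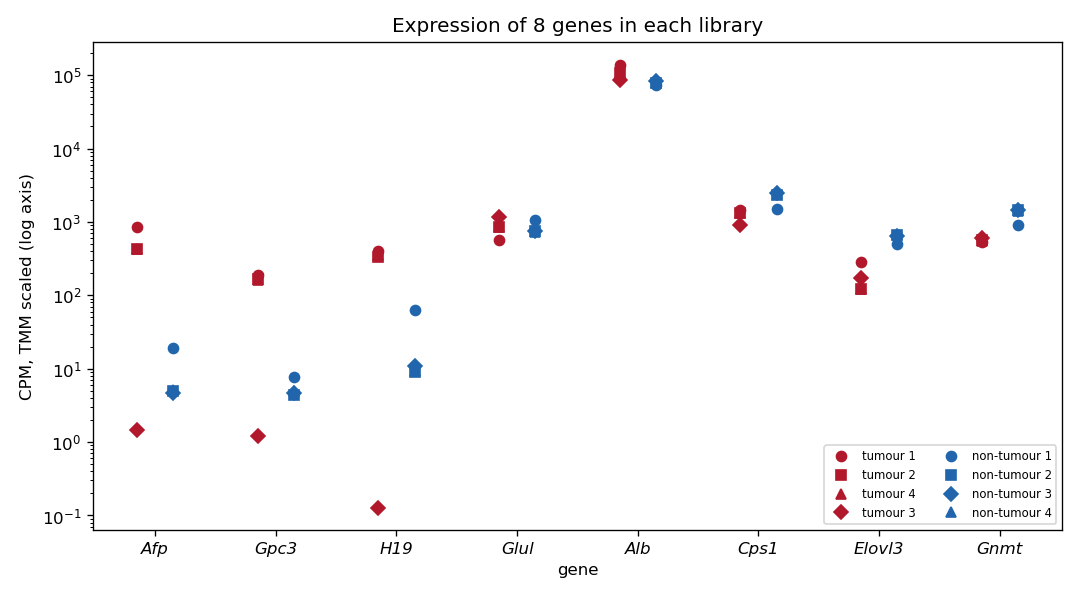
CPM of 8 genes in each library on a log axis, with tumours in red, non-tumour pieces in blue and the symbol giving the replicate number. For Afp, Gpc3 and H19 tumour 3 lies below every non-tumour library, with 1.46, 1.20 and 0.127 CPM, while for Gnmt it lies with the other tumours.

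Gene lists were compared with all other genes by camera with a preset correlation, which called 17 of 40 lists over the 8 libraries, 11 higher and 6 lower in tumours. With an estimated correlation camera called 0 of the 40 lists (5 at an unadjusted p under 0.05), and the adjusted p given second for each list below is that one. The rotation test fry called 8 lists, of which 5 were among the 17: male-biased, female-biased, interferon, MHC and B cell genes. The others were stellate cell (fry adjusted p = 0.0462) and neutrophil markers (0.0280), lower, and adipocyte markers (0.0438), higher. The list tests over 8 libraries rest on the same near-identical libraries as the gene test. Counts of members passing, over all genes or adjusted over the list alone, come from that gene test and are no separate evidence. In it 2321 of 12880 genes had an unadjusted p under 0.05, and 22.3% did in the simulations with no true change. With near-identical libraries counted once and the preset correlation, 19 of 42 lists were called, 15 of them among the 17 and in the same direction. A call in that setting can rest on 1 profile. Camera gave Kupffer cell markers an adjusted p of 3.82e-09 there, though their difference rested on non-tumour 1, as described below. The estimated correlation and fry were not run with libraries counted once. Without tumour 3, over 7 libraries that still include the near-identical ones, more members passed the gene test over all genes, with 14 male-biased, 12 oncofetal, 11 urea cycle, 9 bile acid and 9 p53 target genes the most among the called lists in the direction of their list.

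Genes with higher expression in male than in female mouse liver were lower in tumours. Each of the 17 members had a negative fold change, with a median log2 fold change of -1.13 (adjusted p = 2.97e-25, and 0.277 with an estimated correlation). Over all genes 3 members passed the test, and 15 did when adjusted over the list alone. They included Susd4 at 23.9 ± 6.46 against 52.7 ± 6.82 CPM, Elovl3 at 193 ± 82.3 against 583 ± 106 CPM and the complement gene C6 at 122 ± 38.8 against 280 ± 34.7 CPM. The mean of the list relative to the non-tumour profiles was -0.83 log2 units in tumour 1, -1.87 in tumour 2/4 and -0.95 in tumour 3, against -0.19 and 0.19 in the 2 non-tumour profiles. Female-biased genes were higher (median log2 fold change 1.14, adjusted p = 1.12e-04, and 0.277 with an estimated correlation). Of 15 members 1, Hao2, passed over all genes, and 8 higher and 3 lower members passed when adjusted over the list alone. Cyp2b9, a cytochrome P450 with close paralogs, stood at 107 ± 78.6 against 17.1 ± 12.2 CPM.

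Oncofetal and liver tumour markers were higher as a list (median log2 fold change 2.20, adjusted p = 4.56e-07, and 0.350 with an estimated correlation). Of 16 members 1, Peg3, passed over all genes (12 without tumour 3) and 10 when adjusted over the list alone. Ly6d averaged 49.9 ± 44.98 against 4.76 ± 3.61 CPM. The list score was 2.92 log2 units in tumour 1 and 2.31 in tumour 2/4, but -2.11 in tumour 3. Cholangiocyte markers followed the same libraries (adjusted p = 0.0407, and 0.425 with an estimated correlation), with 0 of 7 members passing over all genes and 3 when adjusted over the list alone. Among them Tspan8 stood at 190, 83.3 and 88.2 CPM in tumours 1, 2 and 4, at 0.254 CPM in tumour 3 and at 3.85 to 7.82 CPM in non-tumour tissue, and Spp1, osteopontin, at 109 ± 93.3 against 25.1 ± 3.81 CPM. The cholangiocyte call was lost without tumour 1, 2 or 4 or non-tumour 1, with an adjusted p of 0.0788 to 0.0905.

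The urea cycle, periportal and bile acid lists were called lower. Some called lists share members, so their calls are not separate results. Cps1, Ass1, Asl, Arg1, Hal, Sds and Gls2 are in both the urea cycle and the periportal list. Cyp7b1 and Slco1a1 are in both the bile acid and the male-biased list, and Tap1 is in both the interferon and the MHC list. Urea cycle and amino acid catabolism genes had a median log2 fold change of -0.54 (adjusted p = 5.26e-11, and 0.293 with an estimated correlation), with 1 of 20 members, Ass1, passing over all genes and 12 when adjusted over the list alone. Slc25a15, the mitochondrial ornithine carrier, stood at 201 ± 12.1 against 282 ± 20.99 CPM and Tat, tyrosine aminotransferase, at 466 ± 16.6 against 808 ± 462 CPM. Periportal genes were lower too (adjusted p = 2.70e-05, and 0.293 with an estimated correlation). Of 18 members 1, Ass1, passed over all genes, and 10 lower and 1 higher did when adjusted over the list alone. Cyp2f2 stood at 605 ± 142 against 1036 ± 187 CPM, while Hsd17b13, a lipid droplet enzyme, was on the other side at 468 ± 86.5 against 317 ± 8.35 CPM. Bile acid synthesis and transport genes were lower (adjusted p = 2.71e-04, and 0.336 with an estimated correlation), with 0 of 22 passing over all genes and 7 lower and 1 higher when adjusted over the list alone. Klb, a coreceptor of fibroblast growth factors, stood at 16.2 ± 2.43 against 22.9 ± 1.604 CPM. The groups overlapped in the scores of these 3 lists. Non-tumour 1 had a periportal score of -0.31, lower than tumour 1 (-0.27) and tumour 2/4 (-0.16). Its urea cycle score of -0.31 and its bile acid score of -0.11 were lower than those of tumour 3 (-0.19 and -0.0013).

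The cholesterol synthesis, lipid droplet and fatty acid synthesis lists were called higher, but non-tumour 1 had a score above that of at least 1 tumour in each. Cholesterol synthesis genes had an adjusted p of 1.11e-05 (0.425 with an estimated correlation), 22 of 23 members had a positive fold change, and 0 passed over all genes and 2 when adjusted over the list alone. Hmgcs1 stood at 742 ± 160 against 426 ± 204 CPM. The cholesterol score was 0.32 in non-tumour 1, above tumour 2/4 (0.20) and tumour 3 (-0.02). Lipid droplet genes had an adjusted p of 7.71e-04 (0.293 with an estimated correlation), with 0 of 15 passing over all genes and 5 when adjusted over the list alone, and Cidec, a droplet coat protein, stood at 8.62 ± 3.06 against 3.69 ± 0.0816 CPM. The lipid droplet score was 0.08 in non-tumour 1, above tumour 1 (0.0031). Fatty acid synthesis genes had an adjusted p of 0.0230 (0.711 with an estimated correlation), with 0 of 17 passing either way. That call was lost with near-identical libraries counted once (adjusted p = 0.460) and without tumour 1, tumour 3 or non-tumour 2, 3 or 4 (0.0525 to 0.241), and non-tumour 1, at 0.48, had a higher score than any tumour.

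Interferon response genes were higher (adjusted p = 4.56e-07, and 0.293 with an estimated correlation), with 25 of 27 members positive, 0 passing over all genes and 5 when adjusted over the list alone. Ifit1 stood at 13.9 ± 3.48 against 7.63 ± 3.19 CPM and Iigp1 at 428 ± 64.8 against 304 ± 9.71 CPM. The interferon score was 0.25 in non-tumour 1, close to tumour 2/4 (0.27) and tumour 3 (0.29). It was 0.50 in tumour 1 and -0.25 in non-tumour 2/3/4. MHC genes had an adjusted p of 3.20e-04 (0.293 with an estimated correlation), with 0 of 14 passing over all genes and 5 when adjusted over the list alone, and their score was 0.07 in non-tumour 1, above tumour 1 (0.03). The MHC call was lost without tumour 3 (adjusted p = 0.0610; 9.58e-08 to 0.0610 over the 8 libraries left out in turn). Targets of p53 (adjusted p = 2.06e-04, and 0.293 with an estimated correlation) and MAPK feedback genes (adjusted p = 2.61e-04, and 0.297 with an estimated correlation) were higher, with 0 of 19 and 0 of 15 members passing over all genes and 2 and 7 when adjusted over the list alone. Phlda3 stood at 3.19 ± 2.00 against 0.925 ± 0.0476 CPM and Dusp6, a MAPK phosphatase, at 54.7 ± 24.3 against 29.5 ± 16.3 CPM. The scores of both lists were -0.10 in tumour 3, below non-tumour 1 (0.05 for p53 targets and 0.22 for MAPK genes), and at least 0.54 in the other tumours.

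Markers of other cell types were measured beside these lists. B and plasma cell markers were higher (adjusted p = 2.61e-04, and 0.277 with an estimated correlation), with 1 of 11 members, Igkc, passing over all genes and 2 when adjusted over the list alone. Igkc, the immunoglobulin kappa constant gene, stood at 38.5 ± 9.32 against 18.7 ± 0.674 CPM and Jchain at 9.96 ± 4.27 against 3.95 ± 0.0192 CPM. T cell markers were lower (adjusted p = 0.0455, and 0.333 with an estimated correlation), with 0 of 9 passing over all genes and 1 when adjusted over the list alone, but not with near-identical libraries counted once (adjusted p = 0.0718) nor without tumour 1, tumour 3 or non-tumour 2, 3 or 4 (0.0610 to 0.240). Cd4 stood at 1.80 ± 0.367 against 3.34 ± 0.374 CPM. Kupffer cell markers were lower (adjusted p = 0.0204, and 0.748 with an estimated correlation), with 0 of 14 passing either way. That call rested on non-tumour 1, whose score was 0.76 against -0.77 to -0.75 in the other non-tumour libraries, and turned to the other direction without it (adjusted p = 0.765). It was also lost without tumour 3 (adjusted p = 0.143). Vsig4 stood at 47.6 CPM in non-tumour 1, at 19.5 to 21.9 CPM in the other non-tumour libraries and at 16.4 to 20.4 CPM in tumours.

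**Figure D3:**
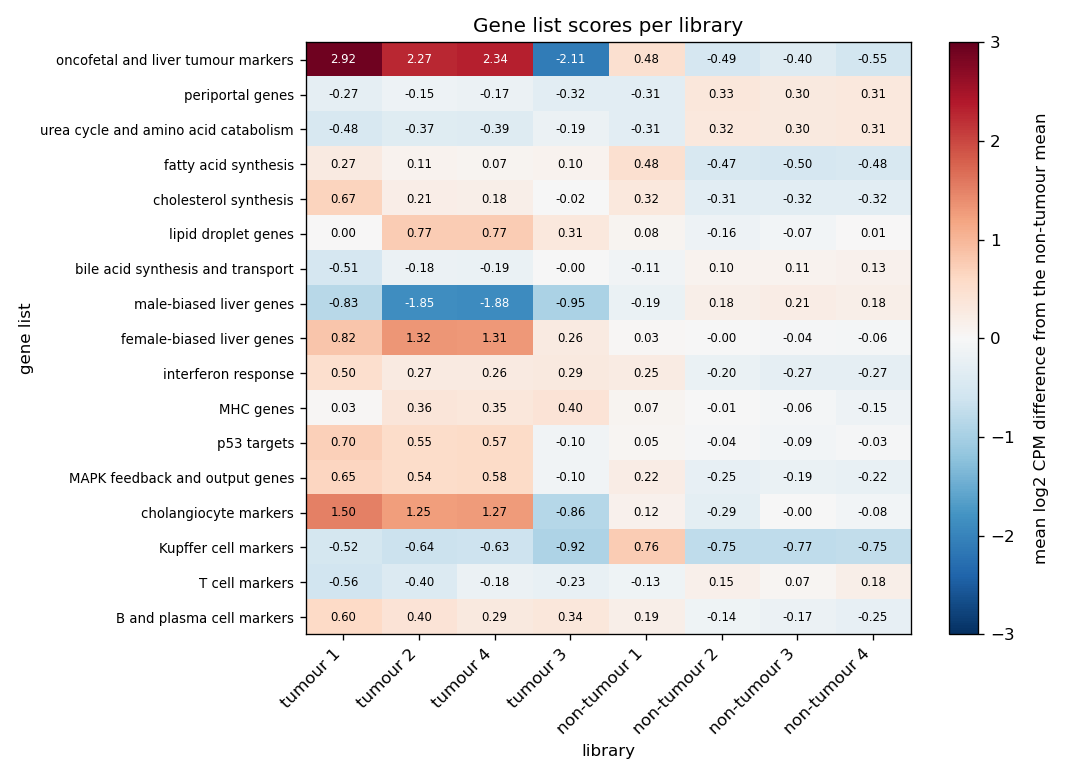
Mean log2 CPM difference of the members of the 17 called lists (rows) from the mean of the non-tumour profiles, in each library (columns), with red for higher and blue for lower. Male-biased genes lie between -1.88 and -0.83 in the 4 tumour libraries, whereas the oncofetal list is at -2.11 in tumour 3 and at 2.27 to 2.92 in the other tumours.

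Camera did not call the other 23 lists over the 8 libraries. Their adjusted p-values were 0.180 for cell cycle, 0.712 for pericentral and Wnt target genes, 0.195 for fatty acid oxidation and PPAR alpha targets, 0.0713 for xenobiotic cytochrome P450 genes, 0.342 for NRF2 targets, 0.712 for glycolysis, 0.448 for acute phase genes, 0.192 for collagen and matrix genes, 0.712 for immune checkpoint genes, 0.469 for chemokines and cytokines and 0.955 for the unfolded protein response. They were 0.712 for immediate early genes, 0.712 for circadian clock genes, 0.849 for mitochondrially encoded genes, 0.755 for hepatocyte markers, 0.784 for sinusoidal endothelial markers, 0.712 for continuous endothelial markers, 0.0713 for stellate cell and fibroblast markers and 0.0563 for monocyte and lipid-associated macrophage markers. They were 0.103 for neutrophil markers, 0.775 for dendritic cell markers, 0.134 for erythroid markers and 0.0713 for adipocyte markers. Over all genes only Ddit3 of the unfolded protein response (log2 fold change 1.03, SE 0.13, adjusted p = 0.0272) and Lrat of the stellate cell list (-0.65, SE 0.10, adjusted p = 0.0394) passed among their members. Several of these lists passed when 1 library was left out. Without tumour 1 these were fatty acid oxidation (adjusted p = 4.61e-05) and stellate cell (0.0327), monocyte (0.0237), erythroid (0.0237) and adipocyte markers (0.0126; 0.0456 without non-tumour 4). Without non-tumour 1 they were cytochrome P450 genes (6.42e-04; 0.0453 and 0.0462 without tumour 2 and tumour 4), acute phase genes (0.00128), collagen (0.0384) and hepatocyte (0.0412), sinusoidal endothelial (0.0493, in the other direction than over the 8 libraries) and monocyte markers (0.00600). Without tumour 3 they were cell cycle (3.58e-04), collagen (0.0183), immediate early genes (0.0171) and monocyte markers (2.07e-05), the last also without non-tumour 2, 3 or 4 (0.00102 to 0.00204). With near-identical libraries counted once, sinusoidal endothelial (adjusted p = 0.0157) and neutrophil markers (0.0411) were called lower and monocyte (0.0182) and mesothelial markers (0.00108) higher. Over the 8 libraries NK cell and mesothelial markers had 2 tested members each, too few for the test, and pancreatic acinar markers had 0.

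The within-group spread asks whether tumours differed from each other more than non-tumour pieces did. Over the 500 most variable genes the mean distance of a library to the centroid of its group was 26.9 ± 14.9 log2 units in tumours and 16.2 ± 7.10 in non-tumour tissue (SD over 4 libraries each, near-identical ones taken singly). The two-sided exact permutation test over 70 arrangements found no difference past its threshold (difference 10.7, p = 0.2). Tumour 3 lay farthest, at 48.5, and without it the difference turned to -6.14. With near-identical libraries counted once the difference was 18.6, and the exact test over 10 arrangements gave p = 0.2 and cannot go below 0.1. In that setting the 2 non-tumour profiles lie equally far from their centroid by construction. A centroid of 2 profiles also lies closer to its members than a centroid of 3, so 18.6 cannot be compared with 10.7.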

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

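The tests of the near-identical tumour libraries, of exchanged labels, of the splits of the 5 profiles, of the matched lists and of counting libraries once were chosen after the results were seen. A library was singled out where its gap to the rest of its group exceeded Dixon's critical value for 4 samples, as a part of the group's range, which chance does in about 1 of 20 groups. Of 40 sets of 4 libraries, 14 met this, 11 of them through non-tumour 1, as follows from the other 3 non-tumour libraries being nearly identical.

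Non-tumour 1 stood apart in Afp (19.4 CPM), H19 (63.2 CPM), Glul (1072 CPM), Cps1 (1510 CPM), Cyp7a1 (75.3 CPM) and the haemoglobin share (0.0624%). It also stood apart in the scores of oncofetal markers (0.48), male-biased genes (-0.19), clock genes (-0.13) and Kupffer cell markers (0.76) and in its distance to the group centroid (26.8). Tumour 3 stood apart in Gpc3 (1.20 CPM; 163 to 192 CPM in the other tumours) and in the oncofetal score (-2.11). The 10 most abundant genes took 26.4% of the counts in tumour 1 and 22.4% to 22.7% in the other tumours.

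The first pattern is the near-identical libraries. Immunoglobulin V genes, whose use differs between B cell populations, agreed within counting noise between tumour 2 and tumour 4 (chi-square per degree of freedom 0.46 over 15 genes; 3.83 to 16.7 in the other 5 tumour pairs), consistent with 1 RNA sample read more than once. Such agreement is not specific to 1 RNA sample, since values of 0.819 (8 genes) and 0.69 (5 genes) were found between tumour 1 and non-tumour 1 and 2, and over 30 genes the agreement was closer than in all but a share of 0.0029 of 10000 lists of other genes matched on reads, for which no cause was tested. Between non-tumour 2, 3 and 4 they differed beyond counting error, the only error that test covers (permutation test, p = 0.0078, 17 genes, 242 reads), and a share of 0.0243 of such matched lists, which also carry the noise of preparation and amplification, differed as much, which argues weakly against repeated reading of 1 RNA sample for these 3. Separate pieces or preparations from 1 liver were not tested and stay open for both sets.

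The second pattern is tumour 3, which lacks the oncofetal markers of the other tumours. An exchange of labels with a non-tumour library needs a partner that carries the markers. In the nearest one, non-tumour 1, the list median lay -1.88 log2 units from tumour 2/4 (SE 0.41 over the 16 list members). This argues against a partner with markers at the level of the other tumours, but not against one with lower levels. Afp and H19 stood at 19.4 and 63.2 CPM in non-tumour 1, above the other non-tumour libraries. An exchange with non-tumour 1, a single wrong label or an exchange with an outside sample thus stays open. A piece with little tumour tissue should show a small part of every shift. Tumour 3 showed a part of 0.394 for 78 genes lower in the other tumours (95% bootstrap interval 0.232 to 0.562) and of -0.286 for 447 higher ones. Both sets were selected on the same non-tumour values that tumour 3 was measured against, which can raise the part. The interval redraws genes of 1 library, so it does not measure the spread between tissues. The higher genes met the bound set in advance against a piece with little tumour tissue and the lower genes did not. That explanation could thus not be decided, and a tumour of another kind is an untested biological explanation.

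The third pattern is the 56 calls. Of the 35 splits of the 8 libraries into 4 and 4, 2 gave as many genes, the real one included, but only 3 splits keep the near-identical sets whole (56, 3405 and 0 calls), too few for a test of chance, and the other 32 called 0. The split with 3405, which exchanges tumour 3 and non-tumour 1, rests on the same repeated libraries; counted once edgeR called 6 genes for it and 3080 had an unadjusted p under 0.05, the highest of the 10 splits of the 5 profiles, against 0 and 451 for the real one. Counting near-identical libraries once left 0 of the 56 calls, while their median absolute log2 fold change went from 0.98 to 0.91 and the median SE from 0.14 to 0.21. Whether fewer profiles alone could give this was not settled. In the simulations of 3 against 2 libraries, 97.4% of genes changed by 2 log2 units and 26% of those changed by 1 were recovered. Near-identical libraries entering as separate replicates could give the 56 calls. Simulations with no true change and the same sets of repeats called 181 to 447 genes. They gave every gene the same dispersion, and their repeats differed less than the real ones, by counting noise alone.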

How the results depend on the processing

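The count of 56 genes was 29 with library size only, 85 without an expression filter, 786 with DESeq2, 6346 with limma voom and quality weights, 0 with edgeR against a 1.5-fold change (485 at an unadjusted p under 0.05), and, in settings chosen after seeing the data, 0 with near-identical libraries counted once (2 with DESeq2 and 0 with voom on them) and 5 when tumour 3 was also left out. Leaving out 1 library gave 0 to 1798 genes: 0 without tumour 2, tumour 4 or non-tumour 2, 3 or 4, 65 without tumour 1, 766 without non-tumour 1 and 1798 without tumour 3. Other scalings, the CPM filter and leaving out abundant genes gave 55 to 61. The number of called lists, 17, was 0 with an estimated correlation and 8 with fry, and 16 to 21 in the other settings. The spread difference was 9.30 to 11.2 in the planned settings over 8 libraries and ranged from -6.14 (without tumour 3) to 19.7 when 1 library was left out. The 23 named genes that were called kept their direction and lost the call with libraries counted once. The causes of these changes, fewer samples among them, were not settled. Depth limits genes under 0.137 to 0.205 CPM, which a count of 0 still allows.

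By the rule set in advance, the replicate numbers did not pair the samples. Of the 4 same-number correlations 2 exceeded 0.1 (0.35, -0.15, 0.29 and -0.12), as with 2000 genes. Tumour 2 and tumour 4 correlated best with non-tumour 1, while tumour 1 and tumour 3 correlated best with their own number. This test cannot decide whether a number marks 1 mouse. Tumours 2 and 4 were nearly the same, as were non-tumour 2, 3 and 4, so the 4 correlations are not separate tests. With the replicate block edgeR called 0 genes (2264 at an unadjusted p under 0.05) and camera 19 lists.

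Directions that turned belonged to results not called, except Kupffer cell markers. The unfolded protein response turned with the CPM filter (adjusted p = 0.979), the block (0.871), fry (0.949) and libraries counted once (0.473; 0.0468 without tumour 3). Counted once, glycolysis (0.731), mitochondrial genes (0.833), hepatocyte (0.628) and continuous endothelial markers (0.393) turned, and without tumour 3 fatty acid oxidation (0.282), NRF2 targets (0.861), glycolysis (0.795), acute phase genes (0.0525) and hepatocyte markers (0.747). Log2 fold changes turned for Glul (counted once -0.0801, -0.0923 with DESeq2 and -0.27 with voom; -0.36 without tumour 3), Npas2 (counted once -0.11 and -0.14 with DESeq2; -0.18 with the block) and Arntl (0.26 without tumour 3; 0.0538 with voom).

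Leaving out 1 library turned these results at least once, with log2 fold changes of -0.12 to 0.21 for Glul, -0.19 to 0.39 for Npas2 and -0.40 to 0.20 for Arntl. The adjusted p ranged over 3.58e-04 to 0.784 for cell cycle, 0.0610 to 0.903 for pericentral genes, 6.42e-04 to 0.608 for cytochrome P450 genes, 0.0183 to 0.838 for collagen, 0.488 to 0.906 for checkpoint genes, 0.0171 to 0.856 for immediate early genes, 0.297 to 0.804 for clock genes, 0.367 to 0.992 for mitochondrial genes, 0.0493 to 0.881 for sinusoidal endothelial, 3.98e-04 to 0.765 for Kupffer cell and 0.318 to 0.964 for dendritic cell markers. It ranged over 0.250 to 0.992 for the unfolded protein response, 4.61e-05 to 0.657 for fatty acid oxidation, 0.0523 to 0.803 for NRF2 targets, 0.00128 to 0.784 for acute phase genes and 0.105 to 0.915 for continuous endothelial markers.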

Other observations

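The tests of the clock genes and of imprinted genes were chosen after the values were seen. The clock genes of tumour 3 stood apart from those of the other 7 libraries, and those named here were chosen after their values were seen. Arntl, which drives the clock, stood at 2.09 CPM in tumour 3 and at 17.0 to 23.2 CPM elsewhere, and its partner gene Npas2 at 0.761 against 4.98 to 8.24 CPM. The output gene Dbp stood at 85.3 CPM against 3.99 to 14.3 CPM, and Per3 at 18.6 against 1.16 to 2.73 CPM. Against the other profiles the median log2 difference was -2.94 for the 3 activators and 1.57 for the 8 output genes tested. Such opposite movement is consistent with tissue taken at another phase of the day, which the labels do not record; a clock altered in the tumour itself was not tested.

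On the first principal component of log2 CPM (52.8% of the variance) tumour 3 lay at 40.3 beside non-tumour 2, 3 and 4 (30.1 to 30.6), and non-tumour 1 at -16.0 on the side of tumours 1, 2 and 4 (-43.9 to -35.5). The second component (19.2%) set tumour 3 apart, at 48.0 against -18.7 to -17.4 in non-tumour 2, 3 and 4. Genes whose tumour and non-tumour libraries do not overlap made up 10.4% of the 12880 genes over 8 libraries. Chance would give 2.86% with 8 separate libraries, but near-identical libraries raise that share. The excess over 2.86% is therefore no evidence of a difference between the groups. Over the 5 profiles the share was 18.4%, against 20% by chance.

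H19 and Peg3 are imprinted, so imprinted genes as a group were compared with 10000 random lists matched on expression. Their median log2 difference from non-tumour tissue was 0.27 in tumour 1, above 98.1% of the lists, but 0.09 in tumour 2/4, above 80.2%, over 21 genes. Without H19 and Peg3, which prompted the test, it was 0.15 in tumour 1, above 86.0% of the lists, so tumour 1 did not keep its place without them. Of the other 19 genes 12 were higher in tumour 1 and 12 in tumour 2/4. Among them were Rian (3.15 and 2.17 log2 units), Meg3 (2.90 and 1.46) and Grb10 (1.71 and 2.31), and a median does not reflect such single large differences. The hypothesis that imprinted genes as a group may be higher in both marker-bearing tumours did not hold in tumour 2/4, nor in tumour 1 without H19 and Peg3.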
